A study of Oncorhynchus mykiss with 57 samples.

How the data were processed

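The series holds 57 arrays, each hybridised with RNA of an exposed and of a control rainbow trout. Per the labels, total RNA was extracted with Trizol and labelled indirectly, the control fish with Alexa Fluor 555 (channel 1) and the exposed fish with Alexa Fluor 647 (channel 2). Per the labels, exposed and control fish of one harvest were otherwise paired at random, and no dye swap is named. The labels give the dose as mg/L of WAF without expanding it. Samples were grouped by tissue, dose and harvest as the labels state, into 10 groups with up to 3 biological replicates of up to 2 technical arrays. One replicate of liver at 10 mg/L after recovery is not in the files, and 1 array of liver at 10 mg/L at 24 h has no technical partner. Per the labels the biological replicates are separate fish, and the p-values of single clones rest on the spread between them. Those of gene lists at the preset correlation described below compare the clones of a list with the other clones. They do not rest on the spread between fish in the same way.

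Per the file headers, each scanner file gives the median intensity and the median local background intensity of every spot and channel, without background subtraction. Per the file headers, the same files give the percent of a spot's pixels above background or saturated, and a spot score, the flag, whose codes are not explained there. Per the file headers, a column holds the scanning software's own normalized log2 ratio, and the deposited value table holds log2 values per spot whose making is not stated. The deposited log2 values were compared with the scanner values to find their scale, centring and direction. Array medians lay between −0.02 and 0.16, the correlation with the log2 ratio of background-subtracted channel 2 over channel 1 was 0.62 to 0.95 on every array, and the values were therefore read as log2 ratios of exposed over control fish, centred near 0. They correlated with the software's own normalized log2 ratio at 0.81 to 0.97, except for −0.59 on the 2 arrays of replicate 2 of liver at 10 mg/L at 24 h.

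Log2 ratios were computed from the scanner intensities in R 4.3.3 with limma 3.58.1. Local background was corrected by normexp with an offset of 50, each array was normalized by global loess, control spots (1243 per array) had no weight in the loess and were left out, and 3 spots with the rarest flag code were left out as bad. Spots of one clone were averaged, then technical arrays of one biological replicate. A linear model with one mean per group was fitted for each tissue with empirical Bayes variances, a log ratio of 0 was tested in each group, and differences among harvest times, doses and tissues were tested as contrasts or F tests in the same kind of model. P-values were adjusted by the Benjamini-Hochberg method over all 16029 clones of a comparison, with the threshold at 0.05. Because no dye swap is named, a log ratio against 0 holds a clone's dye bias along with the effect of exposure. The test of a group minus the mean of the other groups of its tissue removes both a constant dye bias and any effect the groups share. Where a replicate was left out and 1 stayed, that one was assumed to vary like the other groups.

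Gene names were those of the files. None of the clone IDs matched the reference table of gene symbols (0 matches). Clones were named by a rule written before the data were examined, as were the planned processing choices and their alternatives: the 12 largest and 12 smallest named clones past the threshold with the same sign in every replicate, the 10 with the smallest p where fewer than 5 passed or for tests among groups, and up to 4 members per gene list with the smallest p. For a gene with several clones the clone picked by the rule stands, with the number of its clones that have the same sign in the group and the number of these past the threshold. CYP1A clones are given one by one instead, and among the tests between groups this number is given for gill against liver only. Clones with only a code for a name were left out. The text prints a part of these. Clones outside the rule were chosen after their values were seen: CYP1A, rcd1, cytochrome b5 and UDP-glucuronosyltransferase in the groups where they did not pass, CB501070 in gill, in liver at 2 mg/L at 24 h and at 10 mg/L at 96 h, CA044359 in that liver group, rcd1 in liver at 96 h, metallothionein A in gill after recovery, and the single-clone differences between doses and tissues. Where a clone never stood above background in one channel, the fold is a lower bound from the lowest signal of that channel that was above background, and it stays open to dye bias.

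A clone was called above background where its intensity exceeded local background plus 1 background SD. Gene lists (26, of at least 4 clones) were matched by name and tested with limma camera at a preset correlation of 0.01, adjusted over the lists of a comparison, in 19 comparisons. Counts over the list alone use p-values adjusted within the list. Replicates above or below are those whose list median lay above or below the median of all clones. Some names matched a list by a chance of spelling, and the test without these was added after the data were seen.

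Alternatives written before the data were examined were no background correction, print-tip loess, median centring, leaving out dim clones, every array with the replicate as a random block, the deposited table, a replicate block, leaving out each replicate, the group fitted alone, the group minus the other groups of its tissue, and for lists an estimated correlation and limma fry. Chosen after seeing the data were turning the sign of replicate 2 of liver at 10 mg/L at 24 h, a dye term for that replicate, array weights, and lists without false name matches at the preset and at an estimated correlation. The closing section gives their effect.

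The models were tested on simulated log ratios, drawn as independent normal noise with each clone's residual SD, with 200 of 16029 clones changed. The simulation holds no dye bias and no correlation between clones, so its false calls do not measure those in the data. A change of 1 log2 unit was recovered for 65% of clones in gill at 96 h, 74% in liver at 10 mg/L at 96 h, 45% among harvest times in liver at 10 mg/L and 78% between gill and liver, and a change of 2 log2 units for 98%, 99%, 86% and 100%, with 9, 10, 4 and 6 false calls. The median signal over background of the exposed channel was 2.06 to 3.55 in the gill groups and 2.16 to 3.77 in the liver groups, and that of the control channel 3.78 to 5.54 and 4.12 to 5.54. The median share of spots above background was 57.6%, 61.4% and 77.5% in gill at 24 h, 96 h and after recovery. Figures were drawn with python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Slide or scan batches are not given in the sources used here.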

Results

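Rainbow trout were exposed to crude oil at 0.4, 2 or 10 mg/L. Liver was taken at 2 and 10 mg/L at 24 h, at 96 h, and after 96 h of exposure and 96 h of recovery, and at 0.4 mg/L at 24 h only. Gill was taken at 10 mg/L only, at the same 3 harvests. The data were 57 cDNA arrays, 18 of gill and 39 of liver, in 10 groups with 29 biological replicates. Each array compared an exposed fish, in the Alexa Fluor 647 channel, with a control fish of the same harvest, in the Alexa Fluor 555 channel. Groups held 3 biological replicates, except liver at 10 mg/L after recovery with 2. Each array carried 17328 spots, which gave 16029 cDNA clones, and 4331 of these had no gene name. Values are log2 ratios of exposed over control fish, as mean ± SD over biological replicates, and a clone passed at an adjusted p below 0.05 in limma.

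Which transcripts changed in liver 24 h after exposure to 10 mg/L? CYP1A, the monooxygenase induced through the aryl hydrocarbon receptor, rose most. The CYP1A1 clone CB497960 rose by 3.96 ± 0.40 (15.6-fold, adjusted p = 1.67e-07). The CYP1A3 clones CB505556 and CA044359 rose by 3.47 ± 0.16 (11.1-fold, adjusted p = 2.83e-09) and 2.52 ± 0.61 (5.73-fold, adjusted p = 1.07e-06). Another CYP1A3 clone, CB501070, rose by 0.79 ± 0.45 (1.73-fold, adjusted p = 0.0285). Cell differentiation protein rcd1 (CA051849) rose by 1.94 ± 0.17 (3.84-fold, adjusted p = 1.12e-06). Cytochrome b5 (CB511076, 2 of 3 clones higher, 1 called), which passes electrons to P450 enzymes, rose by 1.85 ± 0.49 (3.61-fold, adjusted p = 0.015). UDP-glucuronosyltransferase (CB497940, 3 of 3 clones higher, 1 called), which conjugates oxidised aromatics for excretion, rose by 1.99 ± 0.30 (3.97-fold, adjusted p = 0.0395). The splicing factor clone CB503155 (3 of 4 clones of its gene lower, 1 called) fell at least 1.1-fold (adjusted p = 0.0165), with the exposed channel not well above background. These 8 clones, 7 higher and 1 lower and each with the same sign in all 3 replicates, were all that passed, with 1291 below an unadjusted p of 0.05. Of the 53 clones of the cytochrome P450 and AhR pathway list 4 were higher and 0 lower (5 and 0 when adjusted over the list alone; limma camera adjusted p = 0.000341, 2 of 3 replicates above the median of all clones), but adjusted p = 0.264 with an estimated correlation. The acute phase and complement list (125 clones, 0 higher or lower, 6 and 0 over the list alone, adjusted p = 0.000341, 2 of 3 replicates above) and the metallothionein and iron handling list (90 clones, 0 and 0, adjusted p = 0.000215, 3 of 3 replicates above) also lay higher, each with adjusted p = 0.264 with an estimated correlation. The calls of cytochrome b5 and CB501070 ended without replicate 1 (1.74 and 0.68) or replicate 2 (1.68 and 0.64). That of UDP-glucuronosyltransferase ended without replicate 1 (1.82), 2 (2.06) or 3 (2.09), and that of CB503155 without any one of them. The count was 18 without replicate 3, 1192 with array weights and 204 with the sign of replicate 2 turned. That setting makes the CYP1A values of this replicate negative, so the ended calls of CB497960, CB505556, CA044359 and rcd1 there (1.08, 1.05, 0.38 and 0.61) follow from how it is built.

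Which transcripts changed in liver at 2 mg/L after 24 h? The same 3 CYP1A clones and rcd1 rose. CB497960 rose by 4.17 ± 0.15 (18.1-fold, adjusted p = 7.11e-08), CB505556 by 3.30 ± 0.37 (9.82-fold, adjusted p = 6.68e-09), CA044359 by 2.52 ± 0.28 (5.72-fold, adjusted p = 8.29e-07) and rcd1 by 1.98 ± 0.17 (3.94-fold, adjusted p = 8.29e-07), each in all 3 replicates. Alpha-tectorin (CA039331, 2 of 2 clones lower, 1 called), with its exposed channel not well above background, was the only clone that fell (adjusted p = 0.0173, 3 of 3 replicates), and the remaining clone, CA050894, was not above background in either channel. In all, 6 clones passed, 5 higher and 1 lower, with 2410 below an unadjusted p of 0.05. The clones of UDP-glucuronosyltransferase (CB497940, 1.60 ± 0.06, adjusted p = 0.0864) and cytochrome b5 (CB511076, 0.90, adjusted p = 0.171) did not pass here, and did with every array entered. The CYP1A3 clone CB501070 did not pass either (0.34, adjusted p = 0.24). The metallothionein and iron handling list (90 clones, 0 higher or lower) lay higher with adjusted p = 0.0313 (2 of 3 replicates), and adjusted p = 0.754 with an estimated correlation. Ribosomal proteins (543 clones, 0 higher or lower, 1 and 0 over the list alone) lay higher in 3 of 3 replicates with adjusted p = 0.000867, and adjusted p = 0.754 with an estimated correlation. Exocrine pancreas markers (76 clones, 0 higher or lower) lay higher in 3 of 3 replicates with adjusted p = 0.00119, and adjusted p = 0.0864 with an estimated correlation. This list was meant for digestive enzymes of the pancreas, but only 55 of its 76 clones remained once false name matches were left out. Alpha-tectorin lost its call without replicate 1 and without replicate 3, CA044359 (2.52, adjusted p = 0.0506) with the sign of replicate 2 at 10 mg/L turned, a setting that also widens the CYP1A spread of the fit. The count was 35 in the deposited table, 423 with array weights and 512 with every array entered.

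Did 0.4 mg/L change liver transcripts at 24 h? In limma 0 clones passed, with 2445 below an unadjusted p of 0.05. CB505556 measured 0.15 ± 0.10 (adjusted p = 0.733), CB497960 0.52 ± 0.28 (adjusted p = 0.354) and rcd1 0.23 ± 0.17 (adjusted p = 0.485). Minus the other liver groups, which hold the CYP1A response of the higher doses, CB505556 was lower here (−1.27), CB497960 was at −1.36 and rcd1 at −0.77. Clones on both sides of 0 lay nearest the threshold. Among those at adjusted p = 0.0716, cytochrome c oxidase copper chaperone (CB507314, 2 of 3 clones lower) was lower by 0.81 ± 0.23. With the exposed channel not well above background, histidyl-tRNA synthetase (CB494010) was at least 1.75-fold lower and the antiviral protein viperin (CA042018) at least 1.11-fold lower, but only 1 of 2 viperin clones was lower. Structural maintenance of chromosomes 3 (CB499806), at the same adjusted p, was above background in neither channel and gives no value. Among those at adjusted p = 0.0914, serum amyloid P (CB492757, 1.28 ± 0.42, 3 of 4 clones higher) and carbonyl reductase 1 (CA054769, 0.79 ± 0.11, 3 of 5 clones higher) were positive in all 3 replicates. CB507314, CB492757 and CA054769 passed with every array entered (−0.81, 1.28 and 0.79) and with array weights (−0.83, 1.27 and 0.78). As groups, ribosomal proteins (543 clones, 0 higher or lower, 2 of 3 replicates above the median, adjusted p = 9.96e-09) lay higher, with adjusted p = 0.321 with an estimated correlation. Metallothionein and iron handling (90 clones, 0 higher or lower, 4 and 0 over the list alone, 3 of 3 replicates, adjusted p = 0.00179) lay higher, with adjusted p = 0.33 with an estimated correlation. Exocrine pancreas markers (76 clones, 0 higher or lower, 3 of 3 replicates, adjusted p = 0.00179) lay higher, with adjusted p = 0.123 with an estimated correlation. Array weights gave 927 clones, every array entered gave 539, no background correction 93, and the turned sign of replicate 2 at 10 mg/L gave 276.

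Did the response in liver at 24 h differ with dose? It did for 4 clones in the test among the 3 doses, and all 4 were those above: CB505556 (adjusted p = 1.28e-06), CA044359 and CB497960 (each adjusted p = 8.46e-05) and rcd1 (adjusted p = 0.00071), with 1219 clones below an unadjusted p of 0.05. From 0.4 to 10 mg/L, CB505556 rose by 3.32 (adjusted p = 1.67e-06), CB497960 by 3.44, CA044359 by 2.59 and rcd1 by 1.71, and these 4 were the only clones past the threshold. In that contrast antigen presentation (272 clones, 0 higher or lower, adjusted p = 0.0498) lay higher and exocrine pancreas markers (76 clones, 0 higher or lower, adjusted p = 0.0498) lay lower, each with adjusted p = 0.217 with an estimated correlation and neither past the threshold once false name matches were left out (adjusted p = 0.123 and 0.162). Ribosomal proteins (543 clones, 0 higher or lower, adjusted p = 8e-07) lay lower, with adjusted p = 0.475 with an estimated correlation. The 10 mg/L mean holds replicate 2, which ran against the other liver arrays. The lists of this contrast were not tested without it, so they do not show an effect of dose. Between 2 and 10 mg/L 0 clones passed in limma, and the differences, tested for clones picked after their values were seen, were 0.17 for CB505556 (95% interval −0.34 to 0.69), −0.21 for CB497960 (−1 to 0.57), −0.04 for rcd1 (−0.49 to 0.41) and 0.96 for cytochrome b5 (0.11 to 1.8). Without replicate 3 at 10 mg/L the count among doses was 9, with array weights 97 and with every array entered 17. The 0 in limma with the sign of replicate 2 at 10 mg/L turned follows from the CYP1A values of that replicate being made negative.

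**Figure D1:**
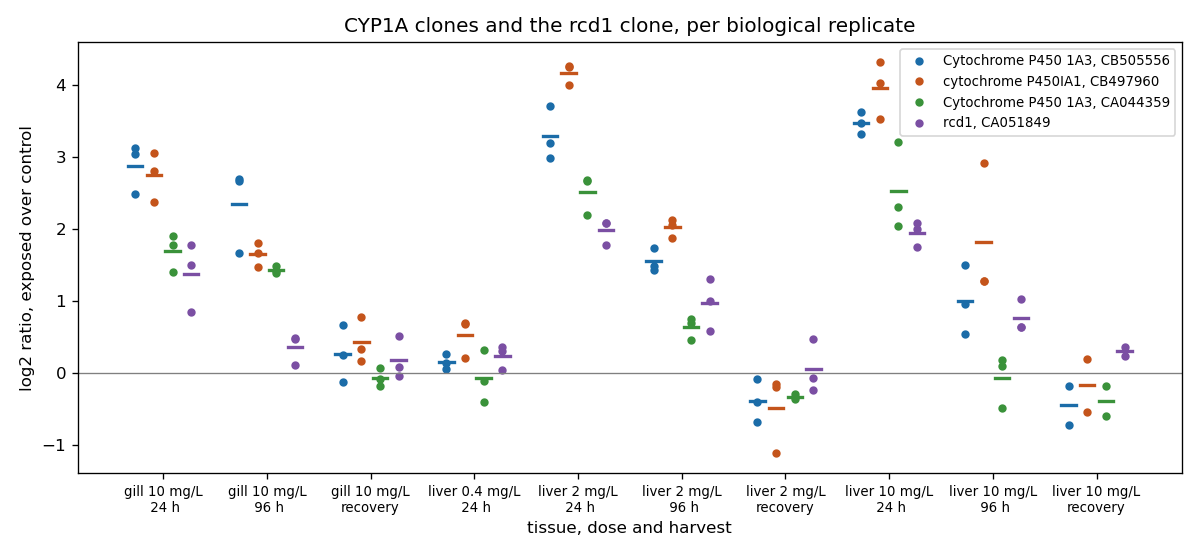
Log2 ratio of exposed over control fish (y axis) by tissue, dose and harvest (x axis) for 3 CYP1A clones and rcd1; each point is a biological replicate and each bar the group mean. In liver at 24 h CB497960 averaged 3.96 at 10 mg/L, 4.17 at 2 mg/L and 0.52 at 0.4 mg/L.

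Which transcripts changed in liver after 96 h at 10 mg/L? Of the 4 CYP1A clones 2 were still higher: CB497960 rose by 1.82 ± 0.95 (3.54-fold, adjusted p = 0.00766) and CB505556 by 1.00 ± 0.48 (1.99-fold, adjusted p = 0.0141), with rcd1 at 0.77 ± 0.23 (1.7-fold, adjusted p = 0.019). CA044359 was at −0.08 (adjusted p = 0.835) and CB501070 at −0.26 (adjusted p = 0.214). Metallothionein B (CB507722, 4 of 4 clones higher, 3 called), a metal-binding protein, rose by 1.30 ± 1.00 (2.47-fold, adjusted p = 0.0281) and the pancreatic protease elastase-2A (CA056317, 6 of 8 clones higher, 1 called) by 1.03 ± 0.34 (adjusted p = 0.0313). Type I iodothyronine deiodinase (CA041779, 2 of 2 clones lower, 1 called), which activates thyroid hormone, fell by 1.14 ± 0.97 (adjusted p = 0.03). Histone H1.0 (CB491022, 6 of 6 clones lower, 2 called), with its exposed channel not well above background, fell at least 1.66-fold (adjusted p = 0.0103). Each of the called clones named so far had the same sign in all 3 replicates. In all, 929 clones passed, 452 higher and 477 lower, with 4205 below an unadjusted p of 0.05. Ribosomal proteins lay higher as a group, with 44 of 543 clones higher and 4 lower (65 and 7 over the list alone). Among the higher ones was L4-A (CB492771, 0.90, adjusted p = 0.0157, 6 of 6 clones higher, 2 called). That list had adjusted p = 1.45e-07 with 3 of 3 replicates above the median, but adjusted p = 0.406 with an estimated correlation. The same list also lay higher at 0.4 mg/L, where no clone passed, at 2 mg/L at 24 h and 96 h, and at 10 mg/L after recovery. A dye bias and a response that these groups share cannot be told apart here. The count was 13 without replicate 1, 206 without replicate 2, 117 without replicate 3 and 528 with print-tip loess. Limma left 0 with the group fitted alone, minus the other liver groups or with a dye term. Calls ended without replicate 1 for CB505556 (1.02), rcd1 (0.83), histone H1.0, elastase-2A (0.89), the deiodinase (−1.04) and L4-A (0.98). They ended without replicate 2 for rcd1 (0.63), metallothionein B (1.25), elastase-2A (1.22) and L4-A (0.83). They ended without replicate 3 for CB505556 (0.74), rcd1 (0.83), metallothionein B (0.83), elastase-2A (0.98), the deiodinase (−0.71) and L4-A (0.88). In the deposited table the deiodinase was −0.08, and minus the other liver groups CB505556 was −0.27, rcd1 −0.14 and CB497960 0.15.

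Which transcripts changed in liver after 96 h at 2 mg/L? The 3 clones that passed were CYP1A and rcd1. CB505556 rose by 1.55 ± 0.16 (2.92-fold, adjusted p = 0.000988), CB497960 by 2.02 ± 0.12 (4.06-fold, adjusted p = 0.0044) and rcd1 by 0.96 ± 0.37 (1.95-fold, adjusted p = 0.0364), each in all 3 replicates, with 1252 clones below an unadjusted p of 0.05. CA044359 was at 0.63 (adjusted p = 0.556). Ribosomal proteins (543 clones, 0 higher or lower, 3 of 3 replicates above the median, adjusted p = 0.00647) lay higher, with adjusted p = 0.937 with an estimated correlation. Calls ended without replicate 1 for CB497960 (1.97), without replicate 2 for CB505556 (1.46), CB497960 (2.09) and rcd1 (0.79), and without replicate 3 for CB497960 (2.00) and rcd1 (0.94). All 3 calls also ended with the group fitted alone, minus the other liver groups and with a dye term, and array weights gave 85 clones.

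Which changes were present in liver after 96 h of recovery? At 10 mg/L, with 2 replicates, CYP1A no longer stood above the control fish (CB505556 −0.45 ± 0.38, adjusted p = 0.204; CB497960 −0.18 ± 0.52, and 0.19 without replicate 3). Minus the other liver groups they were lower (−1.96 and −2.18). Metallothionein A (CB492197) rose by 1.70 ± 0.85 (3.25-fold, adjusted p = 0.0333). Its mean was also above 0 in all other liver groups (0.45 to 1.04), with 0.78 at 0.4 mg/L, and passed in none of them. GDP-L-fucose synthetase (CB508872, 4 of 6 clones higher, 3 called) rose by 1.75 ± 1.05 (adjusted p = 0.0353). Among the clones that fell were serum albumin 2 (CB493984, 5 of 5 clones lower, 1 called) by 1.66 ± 0.83 (adjusted p = 0.0293) and complement C3-1 (CB514355, 9 of 11 lower, 1 called) by 1.37 ± 0.18 (adjusted p = 0.0213). Antithrombin III (CA038790, 2 of 2 lower, 1 called) fell by 1.38 ± 0.01 (adjusted p = 0.0213), and each of the 3 fell in both replicates. In all, 1062 clones passed, 452 higher and 610 lower, with 3861 below an unadjusted p of 0.05; the deposited table gave 400 higher and 361 lower. Of the acute phase and complement list 1 clone was higher and 9 lower (2 and 11 over the list alone; adjusted p = 0.977). Ribosomal proteins had 26 higher and 15 lower of 543 (28 and 16 over the list alone) and lay higher in 2 of 2 replicates (adjusted p = 0.0151), with adjusted p = 1 with an estimated correlation. The count was 119 without replicate 1, 556 without replicate 3, 1 with array weights, 10 minus the other liver groups, 490 with a replicate block and 554 with median centring. Limma left 0 with the group fitted alone or with a dye term. All 5 named calls ended with the group fitted alone and with a dye term. They also ended when either replicate was left out, where the values kept their sign. In the order named, these values were 2.31, 2.49, −2.25, −1.49 and −1.37 without replicate 1. Without replicate 3 they were 1.10, 1.01, −1.07, −1.24 and −1.39.

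At 2 mg/L after recovery, limma passed 0 clones, with 1484 below an unadjusted p of 0.05. CB505556 was at −0.39 ± 0.31 (adjusted p = 0.535) and CB497960 at −0.49, and both were lower minus the other liver groups (−1.89 and −2.55). The acute phase protein serum amyloid P had the lowest values among the clones nearest the threshold (CB497396 −1.74 ± 1.06, CB492757 −1.30 ± 0.79 and CB509749 −1.29 ± 0.69, each adjusted p = 0.248; 3 of 4 clones lower), beside protein disulfide-isomerase A4 (CA064165, 0.51, adjusted p = 0.248; 4 of 4 higher). All 4 of these clones passed with every array entered and with array weights (−1.65, −1.26, −1.29 and 0.52). The endoplasmic reticulum protein folding list (62 clones, 0 higher or lower, 1 and 0 over the list alone) lay higher in 3 of 3 replicates (adjusted p = 2.04e-05), with adjusted p = 0.0602 with an estimated correlation. Array weights gave 87 clones and every array entered 19.

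Did the liver response differ among harvest times? At 10 mg/L 31 clones differed, with 3022 below an unadjusted p of 0.05, led by CB505556 (adjusted p = 1.91e-06), CA044359 (adjusted p = 8.87e-05), CB497960 (adjusted p = 0.000307) and rcd1 (adjusted p = 0.0112). From 24 to 96 h CB505556 fell by 2.47 (adjusted p = 0.000163) and CA044359 by 2.60 (adjusted p = 0.000207), among 15 clones higher and 29 lower. Ribosomal proteins (543 clones, 0 higher or lower, 11 and 1 over the list alone) lay higher at 96 h than at 24 h (adjusted p = 8.19e-06), with adjusted p = 0.5 with an estimated correlation. The 24 h mean in this step holds replicate 2, which ran against the other liver arrays. Neither the clone counts of the step nor the list were tested without that replicate. From 96 h to recovery 1 clone rose, keratinocytes-associated transmembrane protein 2 (CA053070, 1.49, adjusted p = 0.0289). At 2 mg/L the test among times gave 4 clones, CB505556 (adjusted p = 1.61e-06), CB497960 (adjusted p = 1.55e-05), CA044359 (adjusted p = 0.000132) and rcd1 (adjusted p = 0.00117), with 595 below an unadjusted p of 0.05. From 24 to 96 h at 2 mg/L CB505556 fell by 1.75 and CA044359 by 1.89 (each adjusted p = 0.0171). From 96 h to recovery CB505556 fell by 1.94 (adjusted p = 0.00555) and CB497960 by 2.51 (adjusted p = 0.0243); no other clone passed. Exocrine pancreas markers (76 clones, 0 higher or lower) lay lower at 96 h than at 24 h at 2 mg/L (adjusted p = 0.024), with adjusted p = 0.248 with an estimated correlation, and did not pass once false name matches were left out (adjusted p = 0.128). Endoplasmic reticulum protein folding (62 clones, 0 higher or lower) lay higher after recovery than at 96 h (adjusted p = 6.19e-06) and kept its call with an estimated correlation (adjusted p = 0.0433). At 10 mg/L the count was 5 without replicate 2 of 24 h, 406 without replicate 3 of 24 h, 18 without replicate 1 of 96 h and 314 without replicate 3 of recovery. It was 224 with array weights and 5 with a dye term, and the call of rcd1 ended without replicate 2 of 24 h and with a dye term (each adjusted p = 0.0697). Limma gave 0 at either dose with the sign of that replicate turned, which makes its CYP1A values negative and so widens the spread of these clones in the fit.

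Over all harvest times, did 10 mg/L differ from 2 mg/L in liver? In limma 0 clones passed, with 1570 below an unadjusted p of 0.05. Without replicate 3 of recovery at 10 mg/L 17 clones passed, and 15 did with every array entered.

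Which transcripts changed in gill after 24 h at 10 mg/L? CYP1A rose here too: CB505556 by 2.88 ± 0.35 (7.38-fold, adjusted p = 0.000161), CB497960 by 2.74 ± 0.34 (6.7-fold, adjusted p = 3.15e-05) and CA044359 by 1.69 ± 0.26 (3.23-fold, adjusted p = 0.000336). The CYP1A3 clone CB501070 went the other way at −0.58 (adjusted p = 0.0742), negative in all 3 replicates. Rcd1 rose by 1.37 ± 0.48 (2.58-fold, adjusted p = 0.0082) and UDP-glucuronosyltransferase (CB497940, 3 of 3 clones higher, 1 called) by 1.36 ± 1.07 (2.56-fold, adjusted p = 0.0207). Liver fatty acid-binding protein (CB497946, 8 of 11 clones higher, 5 called), a lipid carrier of hepatocytes, rose by 1.39 ± 0.16 (2.63-fold, adjusted p = 0.0116). Hemoglobin beta-1 (CA041804, 9 of 12 clones lower, 1 called) fell by 1.40 ± 0.32 (adjusted p = 0.0116) and the class I antigen-presenting molecule CB502985 (7 of 9 clones of its gene lower, 2 called) by 1.46 ± 0.53 (adjusted p = 0.011). Ribosomal protein L13a (CB494514, 5 of 7 lower, 1 called) fell by 1.37 ± 0.17 (adjusted p = 0.00743) and the epithelial keratin 8 (CB494172, 8 of 10 lower, 3 called) by 1.28 (adjusted p = 0.0115). Each of these had the same sign in all 3 replicates. In all, 1391 clones passed, 606 higher and 785 lower, with 4259 below an unadjusted p of 0.05; print-tip loess gave 436 and 340, median centring 126 and 325, and the deposited values 415 and 421. Of the epithelial keratins, mucins and junctions list 1 of 104 clones was higher and 16 lower (5 and 19 over the list alone; adjusted p = 0.0969), and of the antigen presentation list 8 of 272 were higher and 26 lower (13 and 38 over the list alone; adjusted p = 0.171). Exocrine pancreas markers (76 clones, 6 higher and 1 lower, 8 and 2 over the list alone) lay higher in 3 of 3 replicates (adjusted p = 0.0421), with adjusted p = 0.226 with an estimated correlation, and adjusted p = 0.0544 once false name matches were left out. The count was 11 without replicate 2, 5 without replicate 3 and 5 with the group fitted alone. Calls ended without replicate 1 for UDP-glucuronosyltransferase (1.17) and without replicate 2 for liver fatty acid-binding protein (1.43), hemoglobin (−1.56), CB502985 (−1.68) and keratin 8 (−1.5). They ended without replicate 3 for these (1.45, −1.41, −1.16 and −0.89), rcd1 (1.30), L13a (−1.32) and UDP-glucuronosyltransferase (0.95). Minus the other gill groups limma passed 0 clones, with CB505556 at 1.58, CB497960 at 1.71 and CA044359 at 1.01.

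Which transcripts changed in gill after 96 h at 10 mg/L? Here 4336 clones passed, 1978 higher and 2358 lower, with 6320 below an unadjusted p of 0.05, and every clone named had the same sign in all 3 replicates. CB505556 rose by 2.34 ± 0.59 (5.07-fold, adjusted p = 0.000107), CB497960 by 1.65 ± 0.17 (3.13-fold, adjusted p = 0.000138) and CA044359 by 1.43 ± 0.05 (2.7-fold, adjusted p = 0.000125), while the CYP1A3 clone CB501070 fell by 1.42 ± 0.25 (adjusted p = 0.00041). The 14 kDa apolipoprotein (CA038051, 8 of 8 clones higher, 7 called) rose by 2.54 ± 1.39 (5.83-fold, adjusted p = 0.000618) and serum albumin 1 (CA039492, 6 of 6, 4 called) by 2.49 ± 1.62 (5.6-fold, adjusted p = 0.00169). Serum albumin 2 (CA038122, 5 of 5, 5 called) rose by 2.42 ± 1.67 (5.34-fold, adjusted p = 0.00167) and apolipoprotein A-I (CA037309, 9 of 10, 6 called) by 2.47 ± 1.43 (5.54-fold, adjusted p = 0.000892). Liver fatty acid-binding protein (CB497946, 9 of 11, 6 called) rose by 2.36 ± 0.82 (5.12-fold, adjusted p = 0.000115). Beta-2-microglobulin (CB489190, 22 of 25 clones lower, 16 called), the light chain of class I molecules, fell by 2.84 ± 0.79 (7.17-fold, adjusted p = 8.47e-05). Brain-type fatty acid-binding protein (CK991218) fell by 2.56 ± 0.19 (adjusted p = 0.000107), but only 2 of its 6 clones were lower, 1 of them called. Hemoglobin beta-1 (CA041804, 8 of 12 lower, 7 called) fell by 2.25 ± 0.79 (adjusted p = 0.000131). The ion pump subunit Na/K-ATPase beta-233 (CA062436, 2 of 3 lower, 2 called) fell by 2.17 ± 0.64 (adjusted p = 0.000244), collagen alpha-2(I) (CB498518, 8 of 12 lower, 4 called) by 2.15 ± 0.70 (adjusted p = 0.000393) and keratin 13 (CB493426, 7 of 13 lower, 4 called) by 2.12 ± 0.26 (adjusted p = 0.000107). Without replicate 1, which held the highest values of the 14 kDa apolipoprotein and the albumins, CA038051 was 1.80, CA039492 1.65, CA038122 1.57, CA037309 1.77 and CB497946 1.94, and all kept their calls. Without replicate 2 the count was 2315, fitted alone 2542. Minus the other gill groups it was 437, and the calls ended for CB505556 (0.77), CB497960 (0.06), CA044359 (0.62), CA038051 (1.81), CA039492 (1.49), CA038122 (1.58), CA037309 (1.43) and CB498518 (−1.19).

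Which groups moved in gill at 96 h? Plasma proteins made by the liver (63 clones, 18 higher and 3 lower, 19 and 4 over the list alone) lay higher in 3 of 3 replicates (adjusted p = 0.0438), as did lipid transport and metabolism (191 clones, 42 higher and 18 lower, the same over the list alone, adjusted p = 0.0438), each with adjusted p = 0.68 with an estimated correlation. Exocrine pancreas markers (76 clones, 17 higher and 3 lower, the same over the list alone) lay higher in 3 of 3 replicates (adjusted p = 0.00241), with adjusted p = 0.0991 with an estimated correlation. Lists with more clones lower than higher did not pass with the names as matched: antigen presentation (272 clones, 37 higher and 67 lower, 44 and 69 over the list alone, adjusted p = 0.293), collagen and extracellular matrix (109 clones, 10 and 29, 10 and 31 over the list alone, adjusted p = 0.0916) and red blood cell markers (102 clones, 12 and 24, 13 and 25 over the list alone, adjusted p = 0.2). Once false name matches were left out these 3 lists, then of 109, 105 and 75 clones, passed at the preset correlation (adjusted p = 2.82e-05, 0.0299 and 0.0251), but not with an estimated one (adjusted p = 0.416, 0.723 and 0.723). Only 26 of the 63 clones of the plasma protein list then remained, with replicate medians of 1.6, 0.83 and 0.49, against 0.29, 0.41 and 0.18 with the names as matched. It then had adjusted p = 2.15e-05, and 0.416 with an estimated correlation. Lipid transport and metabolism (185 clones left, adjusted p = 0.0251) and exocrine pancreas markers (55 left, adjusted p = 0.0139) also stayed past the threshold, but not with an estimated correlation (adjusted p = 0.575 and 0.205). Ion transport and carbonic anhydrase had 9 clones higher and 13 lower of 77 (adjusted p = 0.508). On these arrays the median log2 ratio of the channel backgrounds, channel 2 over channel 1, was 1.67, against 0.71 after recovery.

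**Figure D2:**
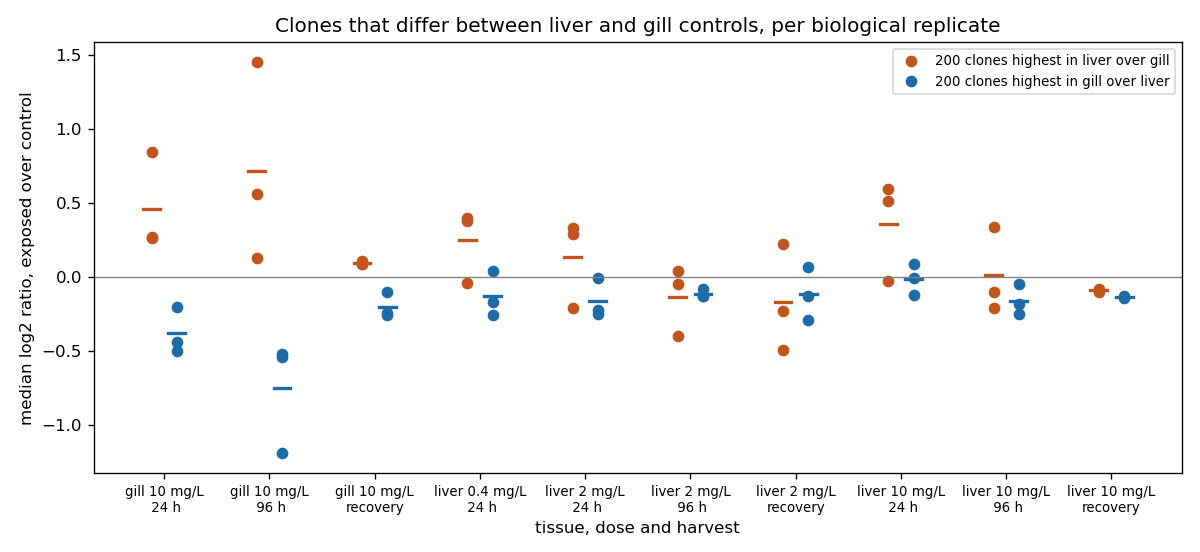
Median log2 ratio of exposed over control fish (y axis) by tissue, dose and harvest (x axis). Shown are the 200 clones with the highest liver over gill signal and the 200 with the highest gill over liver signal. Both sets were picked in control fish, for gill those of the recovery arrays. Each point is a biological replicate of gill or liver and each bar a group mean. In gill at 96 h the liver-high medians were 1.45, 0.56 and 0.13 and the gill-high medians −1.19, −0.52 and −0.54.

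Which changes were present in gill after recovery? In limma 0 clones passed, with 776 below an unadjusted p of 0.05. CB505556 was at 0.26 ± 0.40, CB497960 at 0.43 ± 0.32 and CA044359 at −0.07. Among the named clones nearest the threshold were differentially regulated trout protein 1 (CA046376, 1.40, adjusted p = 0.0716) and GDP-L-fucose synthetase (CB505763, 1.19, adjusted p = 0.0878, 6 of 6 clones higher). Metallothionein A (CB492197) was at 1.04 ± 0.40 (adjusted p = 0.2). All 3 passed without background correction (1.16, 0.85 and 0.93) and with array weights (1.38, 1.18 and 1.09). Minus the other gill groups CB505556 (−2.35), CB497960 (−1.77) and CA044359 (−1.63) were lower after recovery. The metallothionein and iron handling list (90 clones, 0 higher or lower, 1 and 0 over the list alone) lay higher in 3 of 3 replicates (adjusted p = 0.00862), with adjusted p = 0.57 with an estimated correlation. Ribosomal proteins (543 clones, 0 higher or lower) lay lower in 2 of 3 replicates (adjusted p = 0.000551), with adjusted p = 0.654 with an estimated correlation, and collagen and extracellular matrix (109 clones, 0 higher or lower) lay lower in 3 of 3 (adjusted p = 0.00862), with adjusted p = 0.579 with an estimated correlation. Minus the other gill groups 569 clones passed, 42 did with array weights and 10 without background correction.

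**Figure D3:**
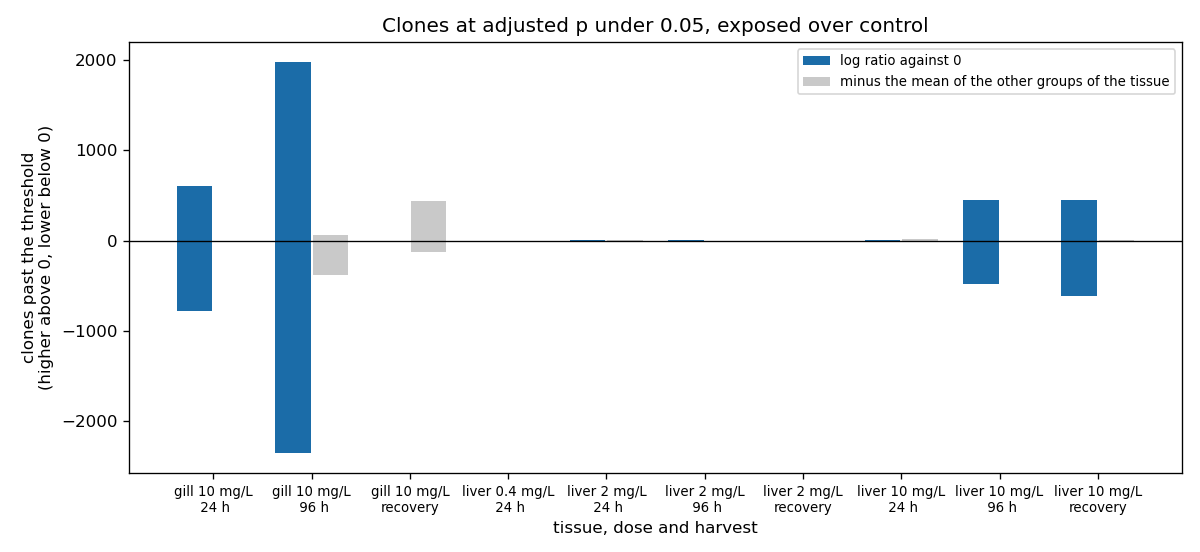
Clones at adjusted p below 0.05 in each group (x axis), with clones higher in exposed fish above 0 and lower below 0 (y axis, clones). Blue bars test the log ratio against 0 (1978 higher and 2358 lower in gill at 96 h), grey bars the group mean minus the mean of the other groups of the tissue.

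Did the gill response differ among harvest times? It did for 365 clones, with 3221 below an unadjusted p of 0.05, among them CB497960 (adjusted p = 0.0123), CA044359 (adjusted p = 0.0123) and CB505556 (adjusted p = 0.0133). Complement C4-B (CA060294, adjusted p = 0.0123) averaged −0.78 at 24 h, −2.06 at 96 h and −0.07 after recovery, and Na/K-ATPase beta-233 (CA051860, adjusted p = 0.0123) averaged −0.81, −1.90 and 0.26. Between 24 h and 96 h limma passed 0 clones, with 1819 below an unadjusted p of 0.05. From 96 h to recovery 892 clones were higher and 279 lower, among them CA060294 (1.99, adjusted p = 0.00442), CA051860 (2.16) and keratin 13 (CB493426, 2.18, adjusted p = 0.00622). In that step epithelial keratins, mucins and junctions rose (104 clones, 12 higher and 0 lower, 14 and 0 over the list alone, adjusted p = 0.0335), with adjusted p = 0.111 with an estimated correlation. Lipid transport and metabolism lay lower (191 clones, 6 higher and 14 lower, 8 and 21 over the list alone, adjusted p = 0.0353), with adjusted p = 0.757 with an estimated correlation. Exocrine pancreas markers lay lower (76 clones, 1 higher and 3 lower, 1 and 2 over the list alone, adjusted p = 0.0136), with adjusted p = 0.111 with an estimated correlation. Ribosomal proteins lay lower (543 clones, 18 higher and 17 lower, 18 and 16 over the list alone, adjusted p = 0.0136), with adjusted p = 0.764 with an estimated correlation. The count among times was 173 without replicate 2 of 24 h, 119 without replicate 3 of 96 h, and 0 in limma without replicate 2 of 96 h (each clone named here then had adjusted p = 0.0731) or without any replicate of recovery (adjusted p from 0.0723 to 0.0994). It was 8 with print-tip loess, 84 with median centring, 0 with the deposited values and 1214 with array weights.

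Did gill differ from liver at 10 mg/L over all harvest times? It did for 57 clones, 11 higher and 46 lower in gill, with 2516 below an unadjusted p of 0.05. Whether gill and liver of one replicate number come from the same fish is not stated, and the model treated them as separate. The closing section gives the smaller count with a replicate block. The ratio was lower in gill by 1.14 for proteasome subunit alpha type 2 (CA038358, adjusted p = 0.00319; 7 of 9 clones lower, 1 called) and by 1.05 for ribosomal protein L13a (CB494514, adjusted p = 0.0283; 6 of 7 lower, 1 called). It was higher by 1.88 for the 14 kDa apolipoprotein (CA044883, adjusted p = 0.0377; 7 of 8 higher, 2 called). The CYP1A3 clone CB501070 was lower in gill by 0.85 (adjusted p = 0.0378), the only one of 3 CYP1A3 clones that was lower. Its call ended when any of 13 single replicates was left out (−0.77 to −0.9), with print-tip loess (−0.64), median centring (−0.81) and the deposited values (−0.85). Lipid transport and metabolism lay higher in gill (191 clones, 5 higher and 1 lower, 16 and 5 over the list alone, adjusted p = 0.00261), and collagen and extracellular matrix lower (109 clones, 0 higher and 2 lower, 0 and 12 over the list alone, adjusted p = 0.00185), each with adjusted p = 0.253 with an estimated correlation. Ribosomal proteins lay lower in gill (543 clones, 0 higher and 8 lower, 1 and 26 over the list alone, adjusted p = 0.00185), with adjusted p = 0.566 with an estimated correlation. At 24 h no CYP1A clone named here passed in the test between the tissues: gill minus liver was −0.59 for CB505556 (95% interval −1.26 to 0.08, adjusted p = 0.371) and −1.22 for CB497960 (−2 to −0.43, adjusted p = 0.146), −0.83 for CA044359 (−1.42 to −0.24, adjusted p = 0.175) and −1.37 for CB501070 (−1.94 to −0.81, adjusted p = 0.101), clones picked after their values were seen. The count was 168, 2 and 1 without replicates 1, 2 and 3 of gill at 24 h, 94, 1 and 118 at 96 h and 1, 2 and 1 after recovery. It was 4, 1 and 123 without those of liver at 24 h, 13, 9 and 1 at 96 h, and 12 and 3 without replicates 1 and 3 of recovery. Print-tip loess and median centring each left 1 clone and the deposited values left 0 in limma, where CA038358 was −1.65, CB494514 −1.08 and CA044883 2.37. The call of CA044883 ended without replicates 2 (1.93) and 3 (1.91) of gill at 24 h, 2 of 96 h (1.97) and 1, 2 and 3 of recovery (1.79, 1.94 and 1.90), and without replicates 1 and 2 of liver at 24 h (1.89 and 1.90), 2 and 3 of 96 h (1.80 and 1.99) and 1 and 3 of recovery (1.93 and 1.82). That of CB494514 ended without replicates 3 of gill at 24 h (−1.03), 2 of 96 h (−1) and 1 and 3 of recovery (−1.06 and −1), and without replicates 2 of liver at 24 h (−0.97), 3 of 96 h (−0.98) and 3 of recovery (−0.99).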

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

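The tests of liver RNA, of dye bias, of scanning and of exchanged dyes below were chosen after the results they bear on were seen; the test of dim spots and all splits of replicates were set before. A sample far from the others stood out in 2 of 60 groups of arrays tested, and chance puts about 1 in 20 there. In liver at 10 mg/L at 96 h, array 1 of replicate 1 had a log2 ratio of channel backgrounds of 1.67, against 0.74 to 0.90 on the other arrays. In liver at 10 mg/L after recovery, array 1 of replicate 1 had a log2 ratio of 0.77 for the CYP1A1 clone CB497960, against −0.61 to −0.38 on the others. A tested difference between groups was found among harvest times for 31 clones in liver at 10 mg/L, 4 in liver at 2 mg/L and 365 in gill, among doses for 4 clones, and between gill and liver for 57.

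Gill had 1391 clones past the threshold at 24 h and 4336 at 96 h but 0 after recovery in limma (776 below an unadjusted p of 0.05), and 4 technical explanations were weighed beside recovery of the tissue. Shifted ratios of dim spots are argued against as the source of most calls: 11.9% of the clones called at 96 h were dim over all gill arrays (95% interval 11 to 12.9). The share among all clones was 35.2%, but the background offset pulls ratios of dim spots toward 0 and so lowers their share among the calls. Liver RNA in the exposed channel of the gill arrays stays open: the lowest replicate correlation with the liver minus gill difference at 96 h was 0.11. Recovery replicates had 0.12 to 0.21, but that difference was built from their own control channels, so these values cannot be set against 96 h. With the control channels of gill at 24 h instead, the correlations were 0.28, 0.03 and −0.04 at 96 h and 0.05, 0 and 0.11 after recovery. The 200 clones highest in liver over gill had medians of 1.45, 0.56 and 0.13 at 96 h and 0.09 to 0.11 after recovery. These clones were also picked with the control channels of the recovery arrays, so the medians after recovery are not independent of the choice. A dye bias that is constant over all arrays stays open for the calls within 24 h and 96 h. After recovery 66.7% of the clones called at 96 h and 76.9% of those called at 24 h had the same sign. Of those called at 96 h, 49.8% had the same sign in liver at 10 mg/L at 24 h, with its replicate 2 discussed below, and 77.8 to 86.6% in the other liver groups. A constant bias would cancel between harvests, and is thus argued against as the whole cause of their difference. The clones called at 24 h, taken with the sign called there, averaged at least 0.62 more in each 96 h replicate than in any recovery replicate. A dye bias that differs between sets of arrays is not covered by this. Different scanning or hybridisation of the recovery arrays also stays open, since the lowest background log2 ratio at 24 h and 96 h stood 0.54 above the highest after recovery.

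Liver at 10 mg/L had 929 clones at 96 h and 1062 after recovery. A constant dye bias of each clone stays open: 87.6% of the clones called at 96 h had the same sign at 0.4 mg/L. Limma called 0 clones there (2445 below an unadjusted p of 0.05). At 10 mg/L at 24 h the share was 48.1%, and 73.5% without the doubtful replicate 2. In replicates 1, 2 and 3 of that group it was 63.1%, 16.7% and 74.1%, so the low share came from replicate 2. As the whole cause a constant dye bias is not excluded either. Clones called in one of these groups, taken with the sign called there, averaged more in the other group than in any replicate at 0.4 or 2 mg/L. In one direction the gap was only 0.03, against an SD between replicates of up to 0.06. A response common to all doses would give the same share, and the group minus the other liver groups passed 0 clones at 96 h.

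Replicate 2 of liver at 10 mg/L at 24 h ran against the other liver arrays, with a log2 ratio of channel backgrounds down to −0.73 where the other arrays of its group reached 0.80. Control fish in channel 2 is argued against by the CYP1A3 clones CB505556 and CA044359, whose mean log ratio in that replicate was 3.42; the CYP1A3 clone CB501070, left out of that mean, was at 1.08. Dyes exchanged while channel 2 holds the exposed fish stay open: the spots without trout cDNA had a mean log2 ratio of 0.55 on its arrays, above the −1.54 to 0.12 of the other liver arrays, but 2 of these were also above 0. Other values lay on the side of an exchange without settling it. Of the clones called in liver at 10 mg/L at 96 h, 16.7% had the same sign in replicate 2, against 63.1% and 74.1% in replicates 1 and 3. On the 2 arrays of replicate 2 the deposited values correlated with the software's own normalized log2 ratio at −0.59, against 0.81 to 0.97 on all others. The median signal over background of these 2 arrays was 5.73 and 5.28 in the exposed channel and 2.24 and 2.25 in the control channel. The other arrays of the group had 2.29 to 3.77 and 4.44 to 6.24. The labels name the same dyes for the 2 arrays of replicate 2 as for all others, so the ratios were left as labelled.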

How the results depend on the processing

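Low signal over background limits the dim clones, and the tests against 0 hold any dye bias of a clone. Except where the construction of a setting shows it, the cause of a change was not tested. Order within each setting: gill 24 h, gill 96 h, gill recovery; liver 0.4 mg/L; liver 10 mg/L 24 h, 96 h, recovery; liver 2 mg/L 24 h, 96 h, recovery; then tests among groups, with counts within 1.5 times the reported one left out.
Print-tip loess: gill 24 h 776, liver 0.4 mg/L 2, liver 10 mg/L 96 h 528, gill times 8, gill against liver 1. Median centring: gill 24 h 451, liver 0.4 mg/L 13, liver 10 mg/L recovery 554, liver 2 mg/L 24 h 13, gill times 84, gill against liver 1. Deposited value table: gill 24 h 836, liver 0.4 mg/L 2, liver 2 mg/L 24 h 35, 96 h 1 and recovery 2, gill times 0, gill against liver 0 in limma. No background correction: gill recovery 10, liver 0.4 mg/L 93, liver 10 mg/L 24 h 13 and 96 h 1700, liver 2 mg/L 24 h 36 and recovery 4, gill times 1210, gill against liver 590. Dim clones left out, so fewer clones tested: gill 24 h 2163, gill recovery 3, liver 10 mg/L 96 h 1406 and recovery 1680, liver 2 mg/L 24 h 24, liver 10 mg/L times 213, gill times 1086, gill against liver 438. Every array with the replicate as a random block: gill 24 h 2342, liver 0.4 mg/L 539, liver 10 mg/L 24 h 22, 96 h 2199 and recovery 2174, liver 2 mg/L 24 h 512, 96 h 5 and recovery 19, liver 10 mg/L times 972, liver 2 mg/L times 7, gill times 1269, doses 17, 10 against 2 mg/L 15, gill against liver 664. Group fitted alone, with fewer samples: gill 24 h 5, gill 96 h 2542, liver 10 mg/L 96 h 0 and recovery 0, liver 2 mg/L 96 h 0. Minus the other groups, which also takes away what groups share: gill 24 h 0, gill 96 h 437, gill recovery 569, liver 0.4 mg/L 1, liver 10 mg/L 24 h 20, 96 h 0 and recovery 10, liver 2 mg/L 96 h 0 and recovery 5. Array weights: gill recovery 42, liver 0.4 mg/L 927, liver 10 mg/L 24 h 1192 and recovery 1, liver 2 mg/L 24 h 423, 96 h 85 and recovery 87, liver 10 mg/L times 224, gill times 1214, doses 97, gill against liver 344. Sign of replicate 2 of liver 10 mg/L 24 h turned: liver 0.4 mg/L 276, liver 10 mg/L 24 h 204, 96 h 1633 and recovery 1770, liver 2 mg/L 24 h 307 and 96 h 0, times 0 at 10 mg/L and 0 at 2 mg/L, doses 0, gill against liver 36; it makes the CYP1A values of that replicate negative (as labelled CB505556 3.63, CA044359 3.21 and CB501070 1.08), so its losses of CYP1A calls follow from how it is built. Dye term: liver 10 mg/L 24 h 19, 96 h 0 and recovery 0, liver 2 mg/L 96 h 0, liver 10 mg/L times 5. Replicate block: liver 10 mg/L recovery 490, gill times 114, gill against liver 18; residuals of replicates of one number correlated at 0.01 on average in gill (9 pairs, 1 over 0.1) and 0.03 in liver (57 pairs, 8 over 0.1), those of different numbers at 0 (18 pairs, 0 over 0.1) and −0.01 (114 pairs, 1 over 0.1). The highest mean correlation was with the own number for 3 of 9 gill and 12 of 20 liver replicates. A batch shared by replicates of one number thus stays open in liver, and the labels name none. A slide or scan batch as a block was not run, since the files give none. Gene lists called fell from 33 to 1 with an estimated correlation, were 34 with limma fry and 56 without false name matches, of which 1 stayed with an estimated correlation.
Leaving out each replicate in turn (lowest to highest): gill 24 h 5 to 1121, gill 96 h 2315 to 4174, gill recovery 0 to 0, liver 0.4 mg/L 0 to 0, liver 10 mg/L 24 h 6 to 18, 96 h 13 to 206 and recovery 119 to 556, liver 2 mg/L 24 h 4 to 9, 96 h 0 to 2 and recovery 0 to 1, times 5 to 406 at 10 mg/L, 4 to 4 at 2 mg/L and 0 to 482 in gill, doses 4 to 9, 10 against 2 mg/L 0 to 17, gill against liver 1 to 168.
Of 1657 values of named clones under these settings 259 no longer passed, 62 passed only there, 15 reversed and the rest kept direction and side of the threshold. Minus the other groups, which hold the CYP1A response, CB505556 was −0.27 in liver at 10 mg/L at 96 h, −1.27 at 0.4 mg/L and −2.35 in gill after recovery, CB497960 −1.36 at 0.4 mg/L and −1.77 in gill after recovery, rcd1 −0.14 in liver at 10 mg/L at 96 h and −0.77 at 0.4 mg/L, and CA044359 −0.07 in liver at 2 mg/L at 96 h. CB497960 in liver at 10 mg/L after recovery was 0.02 with median centring, −0.54 without replicate 1, 0.19 without replicate 3 and 0.09 with a dye term. CA044359 in liver at 10 mg/L at 96 h was 0.09 with print-tip loess, 0.13 without replicate 1, −0.2 without replicate 2 and 0.44 with a dye term. CB501070 in gill at 24 h was 0.21 minus the other groups. CB505556, CB497960, CA044359 and rcd1 in liver at 2 mg/L at 24 h passed throughout, but for CA044359 with the sign turned.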

Other observations

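Across clones, gill at 24 h and gill at 96 h correlated at 0.69, while gill after recovery correlated with other groups at 0.09 to 0.28. Liver at 10 mg/L at 24 h correlated with other groups at 0.02 to 0.16, and gill at 96 h with liver at 10 mg/L at 96 h at 0.48. Of the clones called in gill at 24 h, 55.1% had the same sign in liver at 10 mg/L at 24 h, which holds the doubtful replicate 2, and 88.6 to 93% in the other 6 liver groups, where unlinked signs would give 50.5 to 51.1%. With a liver minus gill difference taken from the control channels of gill at 24 h instead of recovery, the gill replicates correlated at 0.28, 0.03 and −0.04 at 96 h and at 0.05, 0 and 0.11 after recovery. In gill at 96 h, beside the clones of the report, cathepsin L (CB511609, 8 of 12 clones lower, 4 called) fell by 1.92 and cathepsin Z (CK990546, 3 of 4 lower, 1 called) by 1.74. The class II clone CA043705 (7 of 8 lower, 4 called) fell by 1.69 (adjusted p = 0.000107) and ferritin H (CB496534, 13 of 20 lower, 5 called) by 1.62. Hemopexin (CA037805, 6 of 6 higher, 2 called) rose by 1.16.

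The replicates were also split in other ways, with 4 splits for each group of 3 replicates against 0, too few to judge; liver at 10 mg/L after recovery, with 2 replicates, was not split. The real and highest other counts were 1391 and 0 for gill at 24 h (1 split of 4 as large), 4336 and 0 at 96 h (1) and 0 and 0 after recovery (4). For liver they were 0 and 0 at 0.4 mg/L (4), 8 and 204 at 10 mg/L at 24 h (3), 929 and 0 at 96 h (1), 6 and 1 at 2 mg/L at 24 h (1), 3 and 0 at 96 h (1) and 0 and 1 after recovery (4). Of 100 splits, the real one among them, 10 gave as many clones among harvest times in liver at 10 mg/L (31, highest other 322). These splits also move the doubtful replicate 2 of 24 h, without which the count was 5. They thus cannot tell chance from the effect of that replicate. Splits as large, the real one among them, numbered 1 of 100 in liver at 2 mg/L (4, highest other 2) and 1 in gill (365, highest other 116). They numbered 4 among doses (4, highest other 4), 1 for gill against liver (57, highest other 0) and 100 for 10 against 2 mg/L (0, highest other 1).

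The spots without trout cDNA had low signal over background in the exposed channel, with medians of 1.13 for GFP and 1.17 for Arabidopsis in gill and 1.16 and 1.19 in liver. In the control channel they were 1.58 and 1.87 in gill and 1.73 and 2.28 in liver. The 28 technical pairs correlated at −0.10 to 0.52 across clones.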
